A study of Mus musculus with 2 samples.

How the data were processed

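Mouse lung cells were profiled with 10x Genomics single-cell RNA sequencing in 2 libraries, 1 per group. Mice of the control group lacked the Scgb1a1-CreERT driver, a tamoxifen-inducible Cre recombinase under the promoter of the airway secretory cell gene Scgb1a1, and mice of the Goblet-Y/T group carried it. All received 75 mg/kg tamoxifen by intraperitoneal injection for 5 days, and lungs were taken 7 days after the last dose. Per the labels' protocols, live cells were sorted into CD45-positive (immune) and CD45-negative (all other) fractions, which were then combined in equal parts before loading. The number of animals behind each library is not given in the sources used here.

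The authors deposited, for each library, a matrix of raw UMI counts per gene and cell barcode together with its gene and barcode names. Cell Ranger 3.1.0, Seurat 5.0.1 and the genome build mm10 are named in the submitters' processing notes, without a role for each. The annotation release was not given in the sources used here. The values were whole numbers whose totals differed between barcodes and libraries, and 28339 of the 28692 gene IDs matched the GENCODE annotation of mm10 (GRCm38), from which coordinates were taken. Counts per gene do not show which exon a read covered, so a deletion of 1 exon can leave the count of a gene as it was.

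Barcodes with 500 or more genes and at most 10% mitochondrial UMIs were kept, and doublets called in each library by Scrublet (scanpy 1.11.5, expected rate 0.8% per 1000 cells) were removed. Both libraries were clustered together without batch correction. The steps were 2000 variable genes, 40 principal components, 15 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), which gave 38 clusters. Each cluster was named after the cell type whose markers were highest in it, out of 42 marker sets written before the data were examined, where 3 or more of these markers were each seen in at least 10% of its cells. All names therefore mean cells like that type, for example AT2-like for alveolar type 2 cells. A cluster in which a second type reached 75% of the score of the first was called mixed and left out of the comparisons. That cluster held 21 control and 42 Goblet-Y/T cells.

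With 1 library per group there is no measure of the spread between animals, so no test across groups was possible and no p-value is given. Shares of classes were taken within the CD45-positive or the CD45-negative classes, with exact Clopper-Pearson 95% intervals. For gene levels, the UMIs of a class were summed per library and divided by the class total, scaled to a fixed total (CPM). The log2 ratio of CPM, Goblet-Y/T over control, was given a 95% interval from the exact binomial distribution of the counts. These intervals cover counting error only and do not say how animals differ. Those of gene levels treat UMIs as independent and leave out the spread between cells. They can therefore be too narrow even for these libraries, most of all where few cells hold a gene's UMIs. Classes with 50 or more cells in both libraries were compared, 11 in all. Where a gene had a count of 0 in a library, the ratio was taken against a floor of 3 counts over the class.

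From 30 gene lists written before the data were examined, members with 20 or more UMIs over both libraries in the class were used where a list had 5 or more of them, without markers of that class. The median log2 ratio of a list was placed among the medians of 10000 random lists of the same size matched on mean level, as a percentile that describes these libraries. A further 2 lists, sterol synthesis and uptake genes and LXR target genes, were written after the data had been seen. The 30 lists were fixed, but which of them are reported was chosen after their medians had been seen. Counts of single genes over all cells of the CD45-positive or CD45-negative classes, as named from clusters, were added after the data had been seen. For chosen genes, shares of cells with a UMI were compared after each cell had been thinned to 1 number of UMIs, and stand beside the share in a class that should lack the gene. Other shares, given beside single genes, are unthinned. They only show how many cells held a gene's UMIs and are not compared as levels.

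The genes to be named were fixed by a rule written before the data were examined. Of genes with 100 or more UMIs over both libraries and a UMI in 5% or more of the class's cells in the library where they were higher, the 12 highest and 12 lowest log2 ratios were taken in airway secretory cells and the 3 highest and 3 lowest in each other class. The class CPM also had to reach 0.25 of the CPM of the whole library, to leave out free RNA from other cells. Markers of the class, mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, X-inactivation and Y-linked genes and gene models without a name were left out. List members were named with their list.

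The steps were tested on counts simulated from the airway secretory cells of both libraries, with 200 genes changed by known amounts. The intervals held the true log2 ratio for 98.0%, 94.9%, 96.0% and 97.1% of genes changed by 1, -1, 2 and -2, and for 95.3% of 8444 unchanged genes. The simulated class sums were drawn from the same counting model that the intervals assume, so coverage near 95% was built in. Spread between cells, free RNA and the mix of clusters were not simulated. Of 200 unchanged lists, 93.5% lay between percentiles 2.5 and 97.5. The alternatives tried were doublets kept, other limits on mitochondrial UMIs and genes per cell, other cluster resolutions, each library clustered alone, another scaling, the mean of CPM per cell, thinned cells, free RNA subtracted, other UMI minimums for list members and shares of all cells. A further 4 alternatives were added after the data had been seen: airway secretory cells of the cluster led by mucous genes alone, those without it, those with 5000 or more UMIs, and list members past the free RNA rule. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.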

Results

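The deposited data cover 1 control library and 1 Goblet-Y/T library of mouse lung cells, collected 7 days after tamoxifen. The control library held 8395 barcodes with 84824460 UMIs, of which 6086 cells with 71591179 UMIs were kept. The Goblet-Y/T library held 12706 barcodes with 160476426 UMIs, of which 9486 cells with 132658016 UMIs were kept. Kept cells had a median of 11254 UMIs and 3327 genes in the control library and 12820.5 UMIs and 3443 genes in the Goblet-Y/T library. More than 10% mitochondrial UMIs were found in 22.9% of control and 17.7% of Goblet-Y/T barcodes. With 1 library per group there were no replicates, and all intervals below are 95% intervals of counting error.

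The cell makeup of the 2 libraries was compared first. Each class holds cells like the named type, AT2-like or ciliated-like for example, and is written below without that suffix. Alveolar type 2 (AT2) cells, which make surfactant, took 41.2% (39.96 to 42.51) of the CD45-negative cells in the Goblet-Y/T library against 18.5% (17.2 to 19.7) in the control library. Airway secretory cells, the class in which the Scgb1a1 driver is active, took 12.9% (12.1 to 13.8) against 6.75% (5.99 to 7.59). Ciliated cells, which clear mucus, took 15.1% (14.1 to 16.0) against 37.0% (35.5 to 38.5), while mesothelial cells of the lung surface took 26.8% against 29.4%. Basal cells, stem cells of the airway, numbered 60 of 3923 CD45-negative cells in the control library and 1 of 5809 in the Goblet-Y/T library, shares of 1.53% and 0.0172%. Krt5, a keratin of basal cells, had 351 UMIs in the control library and 0 in the Goblet-Y/T library over all CD45-negative classes. That count depends on how clusters were named and leaves out the mixed cluster. Alveolar type 1 cells, the thin cells of gas exchange, made up 1.22% against 0.138%, with 48 and 8 cells.

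Among CD45-positive cells, alveolar macrophages took 61.6% (60.0 to 63.2) in the Goblet-Y/T library and 52.1% (50.01 to 54.28) in the control library. Interstitial macrophages took 13.5% (12.4 to 14.7) against 3.83% (3.06 to 4.73). Neutrophils took 7.67% (6.83 to 8.59) against 16.5% (14.98 to 18.17), T cells 3.80% (3.20 to 4.47) against 9.94% (8.71 to 11.3), and classical monocytes 1.40% (1.05 to 1.84) against 6.07% (5.10 to 7.17). Natural killer cells took 0.413% against 1.77%. Type 2 innate lymphoid cells (ILC2) made up 2.92% (2.39 to 3.52) against 1.87% (1.34 to 2.53), and the dendritic cell type cDC2 3.33% (2.77 to 3.96) against 1.54% (1.06 to 2.16). Because CD45-positive and CD45-negative cells were sorted and combined, only shares within each side can be read, and digestion and sorting can set them too. The gain of interstitial macrophages, 9.71 percentage points, came to 2.10 points with each library clustered alone and 4.04 points with doublets kept, the deficit of neutrophils, -8.85 points, to -3.97 points with 1000 or more genes per cell, and the difference for adventitial fibroblasts, -1.20 points, to 0.538 points with 200 or more genes per cell, 0.426 at resolution 2 and 0.722 with each library clustered alone. Taken over all cells of a library, the differences were 13.4 points for AT2, 3.57 for airway secretory, -14.6 for ciliated, 5.26 for alveolar macrophage, 3.84 for interstitial macrophage, -2.04 for T and -2.88 for neutrophil cells.

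**Figure D1:**
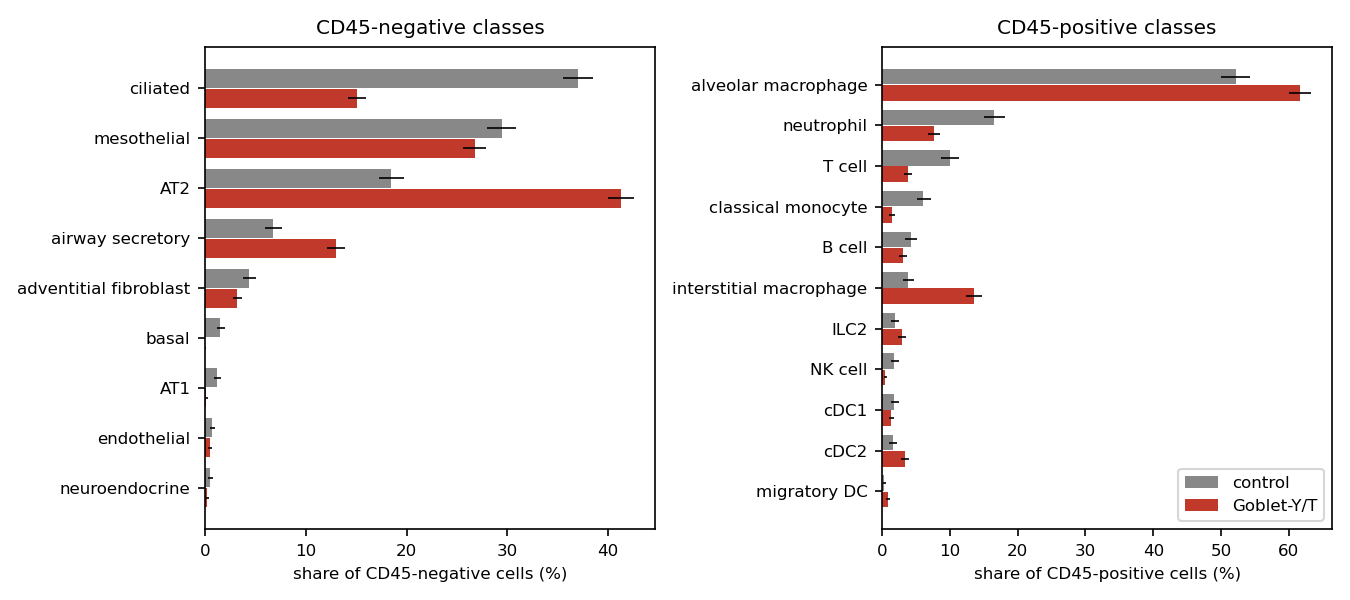
Share of each cell class (x axis, percent) among the CD45-negative cells (left) and CD45-positive cells (right) of the control library (grey) and the Goblet-Y/T library (red). Bars are single libraries and lines are exact 95% intervals of counting error. AT2 cells stand at 41.2% against 18.5% and ciliated cells at 15.1% against 37.0%.

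The genotype label was then examined. Y/T is not spelled out in the labels. Yap1 and Wwtr1, which encodes TAZ, were taken as its candidate reading before the data were examined. They are the paired transcriptional coactivators of the Hippo pathway. Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596, minus strand) was lower in airway secretory cells of the Goblet-Y/T library, at 7.83 CPM (132 UMIs) against 21.5 CPM (125 UMIs), a log2 ratio of -1.46 (-1.82 to -1.09). Wwtr1 (ENSMUSG00000027803, chromosome 3, 57455649 to 57575910, minus strand) stood at 12.6 CPM (212 UMIs) against 21.4 CPM (124 UMIs), a log2 ratio of -0.76 (-1.09 to -0.43). The control levels were 0.597 (Yap1) and 0.353 (Wwtr1) of the CPM of the whole control library. Free RNA was estimated at 13.3% of control and 6.18% of Goblet-Y/T airway secretory UMIs, so it can make up part of these levels. In AT2, ciliated and mesothelial cells, Yap1 had log2 ratios of -0.38 (-0.54 to -0.20), -0.27 (-0.435 to -0.10) and -0.11 (-0.23 to 0.02). Wwtr1 there had 0.34 (0.18 to 0.50), 0.10 (-0.09 to 0.28) and -0.04 (-0.13 to 0.05). In adventitial fibroblasts Yap1 was at -0.67 (-1.31 to -0.05) and Wwtr1 at 0.13 (-0.16 to 0.42). Yap1 was thus lower in all 5 other classes measured, with a median of -0.38, and Wwtr1 in 3 of 6, so a lower Yap1 was not particular to airway secretory cells. In alveolar macrophages Wwtr1 was lower too, at -0.60 (-0.72 to -0.48), and so was Yap1, at -1.39 (-2.45 to -0.33) from 16 control and 18 Goblet-Y/T UMIs, 1.34 CPM against 0.512 CPM. That level was 0.0372 of the CPM of the whole library, at the free RNA level, with a UMI in 1.34% and 0.759% of cells, so it cannot be read as a level of these cells. T cells had 0 Yap1 UMIs in both libraries. Reads outside a deleted exon check nothing about its loss, so these levels cannot show what share of cells lost either gene. With cells weighted equally, Wwtr1 in airway secretory cells came to -1.58. In the cluster led by mucous genes alone, an alternative chosen after seeing the data, Yap1 came to -0.79 and Wwtr1 to -0.39.

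Known target genes of YAP and TAZ were lower in airway secretory cells of the Goblet-Y/T library. Of 19 measured members of the target signature, 17 were lower and 2 higher, with a median log2 ratio of -0.90 (-1.16 to -0.66), at percentile 0.0 of random lists. Ctgf and Cyr61, matricellular proteins and classical YAP targets, had the lowest log2 ratios of all genes open to naming in this class. Ctgf (chromosome 10, 24595442 to 24598683) fell from 135 UMIs in the control library to 7 in the Goblet-Y/T library, a log2 ratio of -5.81 (-7.15 to -4.73). Cyr61 (chromosome 3, 145646976 to 145649981) was at 6.29 CPM against 155.3 CPM, a log2 ratio of -4.63 (-4.93 to -4.33). The control levels of Ctgf and Cyr61 were 0.675 and 0.741 of the CPM of the whole control library, so part of them can be free RNA. Nt5e, the ectoenzyme CD73, was at -2.75, and the Hippo pathway feedback genes Amotl2, Lats2 and Ptpn14 were at -2.33, -1.91 and -1.51. Of 15 measured components of the Hippo pathway, 11 were lower, with a median of -0.24 (-0.48 to -0.01) at percentile 2.71. The medians of the target signature were 0.04 (-0.12 to 0.25) in AT2 cells, 0.08 (0.02 to 0.30) in ciliated cells, -0.06 (-0.13 to 0.02) in mesothelial cells and -0.59 (-0.77 to -0.26) in adventitial fibroblasts. With only 6 measured members each, they were -1.39 (-1.70 to -0.79) in B cells and -0.72 (-0.94 to -0.31) in classical monocytes, so lower levels were not limited to airway secretory cells. The value in B cells came to -0.49 with doublets kept, -0.53 with each library clustered alone and -0.72 with cells weighted equally, and that in monocytes to -0.16 with members of 5 or more UMIs. In airway secretory cells the median was -1.71 when members were limited to genes past the free RNA rule, and -0.48 in the cluster led by mucous genes alone. Both alternatives were chosen after seeing the data.

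**Figure D2:**
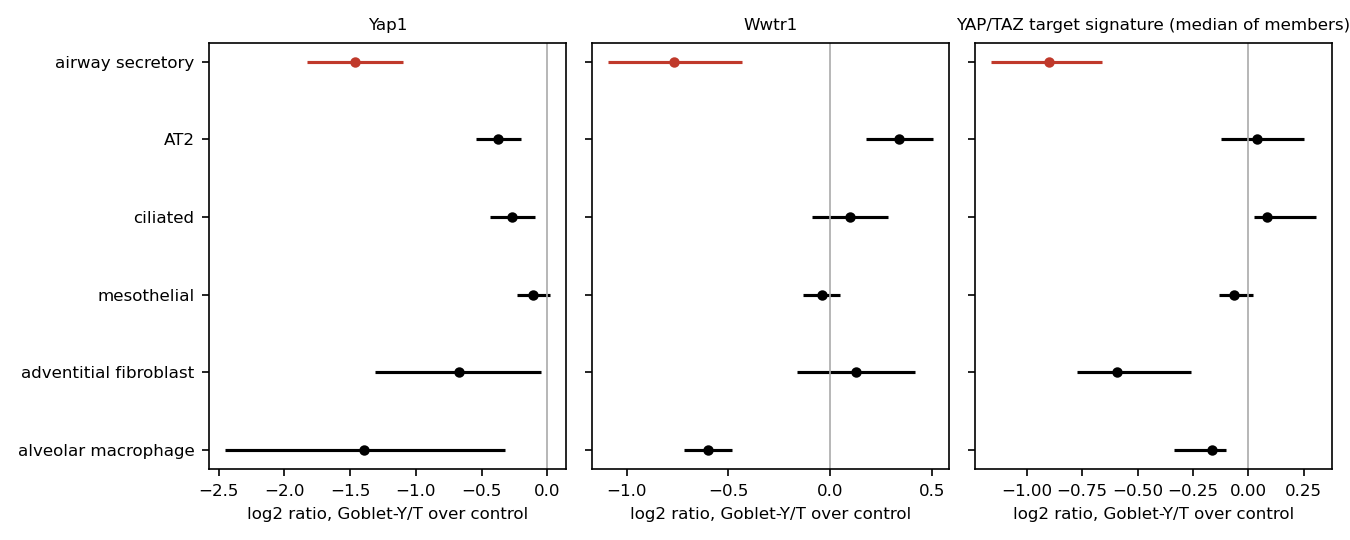
Log2 ratio of CPM, Goblet-Y/T over control (x axis), of Yap1 (left), Wwtr1 (middle) and the median of the YAP/TAZ target signature (right) in 6 cell classes. Points are single library pairs, lines are 95% intervals of counting error and airway secretory cells are in red. The signature is at -0.90 in airway secretory cells and between -0.06 and 0.08 in AT2, ciliated and mesothelial cells, and at -0.59 in adventitial fibroblasts.

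The main comparison asked how airway secretory cells, in which the Scgb1a1 driver acts, differed between the libraries. It rests on 265 control cells with 5800585 UMIs and 752 Goblet-Y/T cells with 16849400 UMIs. Genes of protein folding and several mucous genes were higher in the Goblet-Y/T library, while drug-metabolising enzymes of club cells, junction genes and interferon response genes were lower. All 13 measured genes of the unfolded protein response were higher, with a median log2 ratio of 1.11 (0.99 to 1.15) at the top of the random lists. Among them were the stress transcription factor Ddit3 at 1.68, the endoplasmic reticulum proteins Sdf2l1 at 1.64 and Manf at 1.39, and the chaperone Hspa5 at 1.02. Of 16 measured genes of xenobiotic metabolism, 14 were lower, with a median of -0.98 (-1.03 to -0.84) at percentile 0.0. The cytochrome P450 genes Cyp2a5, Cyp4b1 and Cyp2b10 were at -4.34, -3.20 and -2.23, and the glutathione transferase Gsta3 at -1.38. Without the cluster led by mucous genes this median came to -0.50.

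Goblet and mucous genes were higher on balance, 16 of 25, with a median of 0.46 (0.24 to 0.66) at percentile 99.2. Clca1, a protein secreted by goblet cells (chromosome 3, 145003817 to 145032776), was at 507.0 CPM against 21.9 CPM, a log2 ratio of 4.53 (4.28 to 4.80), and had a median ratio of 5.32 over 7 other classes. The gel-forming mucins Muc5ac and Muc5b were at 2.10 (1.71 to 2.52) and 0.66 (0.61 to 0.71). Fcgbp, a mucus protein, was at 1.99, Agr2, which folds mucins, at 1.60, and Creb3l1 at 1.20, though Agr2 was detected in a lower share of cells (below). In the opposite direction were Bpifa1, an airway surface protein, at -3.74, lactoferrin (Ltf) at -3.69, the membrane mucin Muc16 at -2.28 and the secretoglobin Scgb3a1 at -1.49. Spdef, the goblet cell transcription factor, was at 0.82 (0.23 to 1.46), from 28 and 144 UMIs. The list median was 1.15 in the cluster led by mucous genes alone and 1.15 without it, and without it Spdef and Scgb3a1 turned direction, to -0.07 and 1.41.

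Muc5ac was detected in 16.97% (14.0 to 20.2) of Goblet-Y/T and 6.09% (3.19 to 10.4) of control airway secretory cells thinned to 12000 UMIs, with 157 and 68 shallower cells left out. Mesothelial cells thinned alike had 1.12% and 0 of 722 cells, the latter allowing up to 0.416%. Unthinned shares were 22.6% and 14.3% in airway secretory cells, with median depths of 24411.5 and 24538 UMIs, and 0.965% and 0.0% in mesothelial cells, with 10302.5 and 13297 UMIs. Agr2 had the higher CPM in the Goblet-Y/T library but the lower share of thinned cells, 17.65% (14.67 to 20.95) against 36.0% (29.3 to 43.2). Mesothelial cells thinned alike had 4.12% and 0.0%, and unthinned airway secretory shares were 18.9% and 30.6%. Its CPM and its share thus went opposite ways, and no single direction is read for Agr2. Spdef, at 6.72% (4.85 to 9.04) against 5.08% (2.46 to 9.14), and Muc5b, at 62.2% (58.1 to 66.1) against 55.8% (48.6 to 62.9), had overlapping intervals, with 0.562% and 0.0% for Spdef and 12.9% and 0.970% for Muc5b in mesothelial cells. Clca1 was detected in 12.3% against 7.11% of airway secretory cells and in 10.3% against 0.416% of mesothelial cells, so its share was near that background in the Goblet-Y/T library. Unthinned, the shares in airway secretory cells were 11.4% and 10.2% for Spdef, 63.8% and 44.9% for Muc5b and 16.1% and 6.42% for Clca1.

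Genes of AT2 cells were higher in airway secretory cells of the Goblet-Y/T library, all 10 of the surfactant list, with a median of 1.78 (1.75 to 1.80). Lipocalin Lcn2 was at 3.82, the chemokine Cxcl15 at 2.24, the chitinase-like Chil1 at 2.11 and fatty acid synthase Fasn at 2.00. Lcn2 was higher in 9 of 10 other classes too, with a median ratio of 2.57. Cxcl15 and Chil1 were higher in all 10, with median ratios of 1.56 and 1.79, and the surfactant gene Sftpb, at 1.89 here, had a median of 1.29 over them, beside the larger share of AT2 cells. Cluster 10 of airway secretory cells had AT2 as its second type, with a marker score of 2.01, against 0.593 and 0.416 in clusters 19 and 20. The interferon response was lower, 13 of 15 with a median of -0.64 (-0.90 to -0.47) at percentile 0.36. Epithelial junction and cytoskeleton genes were lower in 11 of 13, with a median of -0.52 (-0.65 to -0.46), among them keratin Krt7 at -1.96 and the claudins Cldn4 and Cldn18 at -1.79 and -1.45, of which Cldn18 turned to 0.64 in the cluster led by mucous genes. Genes of the alveolar transitional epithelium, a state between AT2 and AT1 cells, were lower in 8 of 11, with a median of -0.52 (-0.58 to -0.46). Immediate early genes were higher in 11 of 15, with a median of 0.54 (0.48 to 0.60) at percentile 97.0. The IL-13 response list, 6 of 10 higher, had a median of 0.72 (0.55 to 1.20), but of 0.01 without members at the free RNA level 0.01 at resolution 2, 0.13 with up to 20% mitochondrial UMIs and -0.05 with each library clustered alone. The Notch pathway list, 4 of 7 higher, had a median of 0.44 (0.20 to 0.62), which came to 0.15 in the cluster led by mucous genes and 0.05 without it.

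Among the 12 genes with the highest ratios was Esr1, the oestrogen receptor alpha (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614), with 1697 UMIs against 7, a log2 ratio of 6.38 (5.34 to 7.70). CreERT is itself a fusion of Cre with a modified oestrogen receptor domain, and whether these UMIs came from Esr1 or from the fusion was not tested. The potassium channel Kcnk3 was at 6.23 (3.74 to 11.54) from 218 UMIs against 1, the lipase-related Pnliprp1 at 5.23, the tight junction gene Cldn2 at 4.998 and dermokine (Dmkn) at 4.81. Dmbt1, a mucosal defence receptor, was at 4.64 (2.76 to 7.70) from 145 UMIs against 2, and BC048546 and Lrg1 were at 4.34 and 4.19. The protease inhibitor Spink5, the acute phase gene Saa3 and the neurotrophin receptor Ntrk2, the last from 136 UMIs against 3, were at 4.08, 4.02 and 3.96 (2.39 to 6.26). Among the 12 lowest, besides those above, were Cyp4a12b at -3.71, Fmo6 at -3.68, Sec14l3, also a marker of ciliated cells, at -3.59, Gramd2 at -3.51, the sulfotransferase Sult1d1 at -3.47, the transcription factor Pax9 at -3.34 and Vpreb3 at -3.32. Vpreb3, at 0.267 of the CPM of the whole library, was lower in 4 of 5 other classes with a median of -1.82, and Sec14l3 in 7 of 10 with a median of -0.89, beside fewer ciliated cells and an estimated free RNA share of 13.3% in control and 6.18% in Goblet-Y/T airway secretory cells. Bpifa1 (chromosome 2, 154142880 to 154149219) took 2.21% of control and 0.166% of Goblet-Y/T UMIs, and Scgb1a1 37.4% and 29.8%. Different clusters held most of the class: number 20 held 57.7% and number 19, led by mucous genes, 39.2% of control cells, while number 10 held 68.2%, number 19 20.5% and number 20 11.3% of Goblet-Y/T cells. Cluster 20 had a median of 16438 UMIs in control and 1762 in Goblet-Y/T cells, and such shallow cells weigh on the share of the class and on values with cells weighted equally. Cyp2a5 and Cyp4a12b have near-identical copies, between which counts may be split, and a cluster mostly of 1 library may stand for that library and not for a cell type.

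**Figure D3:**
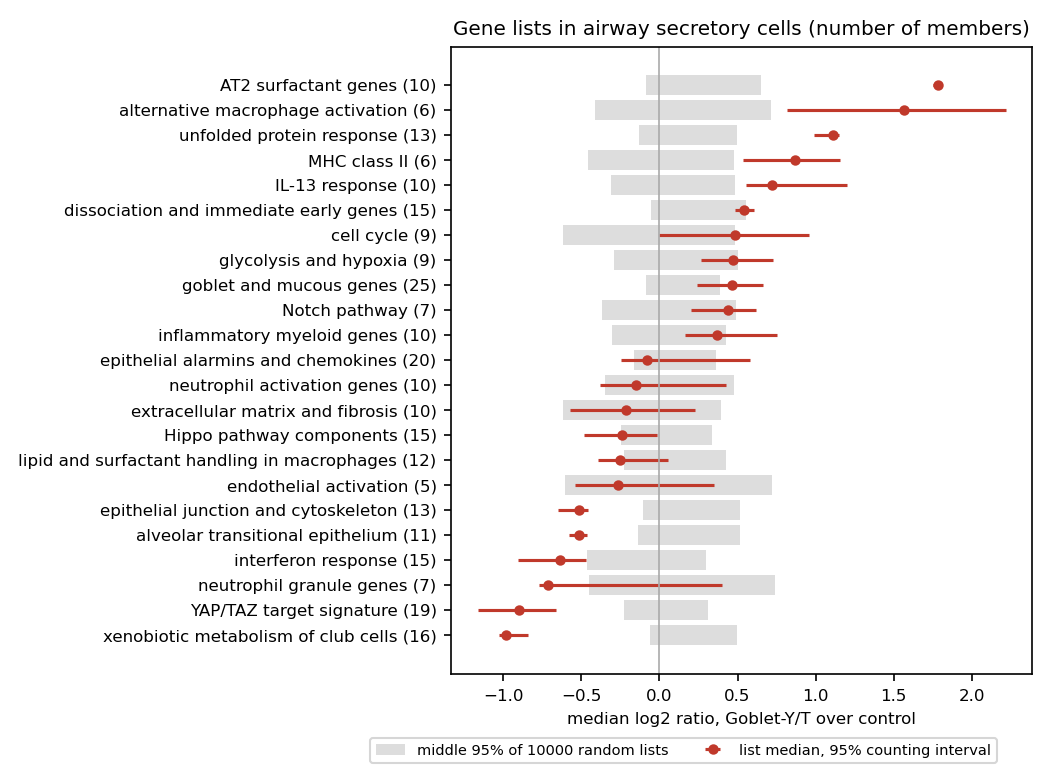
Median log2 ratio, Goblet-Y/T over control (x axis), of each gene list in airway secretory cells, with the number of measured members in brackets. Points are list medians with 95% counting intervals and grey bars hold the middle 95% of 10000 random lists. The unfolded protein response (1.11) and the AT2 surfactant genes (1.78) lie above their grey bars, and the YAP/TAZ target signature (-0.90) and xenobiotic metabolism (-0.98) below.

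AT2 cells, 724 in the control library and 2395 in the Goblet-Y/T library, showed higher cell cycle, transitional and alarmin genes in the Goblet-Y/T library. All 11 measured cell cycle genes were higher, with a median log2 ratio of 3.28 (3.00 to 3.35) at the top of the random lists. The proliferation marker Mki67 was at 2.77 (2.58 to 2.97), topoisomerase Top2a at 3.12, survivin (Birc5) at 3.43 and cyclin Ccnb2 at 3.39. Of the transitional epithelium list, 10 of 11 genes were higher, with a median of 1.63 (1.59 to 1.75), among them Cldn4 at 3.16, clusterin (Clu) at 2.63 and keratin Krt8 at 1.90. Epithelial alarmins and chemokines were higher in 18 of 21, with a median of 0.85 (0.64 to 1.28). Ccl20, a ligand of the receptor Ccr6, was at 6.65 (5.10 to 8.92) from 1110 UMIs against 3, Lcn2 at 2.55 and the alarmin Il33 at 1.53 (1.49 to 1.57). By its ratio Ccl20 would rank among the 3 highest of the class, but it did not pass the naming rule. That rule asks for a UMI in 5% or more of cells and a level above free RNA, so Ccl20 was not read as a level of AT2 cells in general.

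Mki67 was detected in 17.9% (16.3 to 19.5) of Goblet-Y/T and 1.88% (1.00 to 3.19) of control AT2 cells thinned to 7000 UMIs, with 183 and 31 cells left out, and in 1.50% and 0.454% of ciliated cells thinned alike. Unthinned shares in AT2 cells were 21.2% and 3.59%, with median depths of 15970 and 14724.5 UMIs, and in ciliated cells 2.74% and 0.689%, with 11193 and 11762 UMIs. Among genes with UMIs in 5% or more of the cells, the highest ratio belonged to Retnla, a secreted resistin-like protein (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), at 6476 CPM against 51.9 CPM, a log2 ratio of 6.96 (6.84 to 7.09). Retnla was higher in all 10 other classes measured too, with a median ratio of 5.08. Next among these genes were Phox2a at 6.07 (3.58 to 11.38) and the phosphodiesterase Pde1c at 5.99 (3.50 to 11.30), each with 1 UMI in the control library. The lowest were the chemokine receptor Ccr6 at -2.96, Bex2 at -2.92 and the Wnt antagonist Notum at -2.64. Cluster 6 held 88.3% of control AT2 cells and cluster 0 held 67.3% of Goblet-Y/T AT2 cells. The median gene of this class lay at 0.17, and the cell cycle median was 6.48 with each library clustered alone.

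Alveolar macrophages, 1117 and 2240 cells, had higher antigen presentation genes and lower lipid handling genes in the Goblet-Y/T library. All 7 MHC class II genes were higher, with a median of 2.46 (2.30 to 2.57), among them H2-Eb1 at 3.05 and the invariant chain Cd74 at 2.56. Alternative activation genes were higher in 7 of 10, with a median of 1.82 (1.42 to 2.53), and the arginine-degrading enzyme Arg1 was at 3.31 (2.99 to 3.64). Genes of lipid and surfactant handling were lower in 8 of 12, with a median of -0.58 (-0.61 to -0.54), among them the cholesterol exporters Abca1 at -3.00 (-3.18 to -2.83) and Abcg1 at -1.61 and the fatty acid receptor Cd36 at -1.96. Abca1 was lower in every class in which it was measured, so its lower level was not particular to alveolar macrophages. Among 10 targets of the cholesterol sensor LXR, 7 were lower, with a median of -1.05 (-1.17 to -0.95), and all 17 sterol synthesis and uptake genes were higher, with a median of 1.66 (1.50 to 1.69). Osteopontin (Spp1) was at 3.02 and the cytokine Il1b at 2.35. By ratio the extremes were Tarm1 at 6.89 (4.40 to 12.20), a receptor of myeloid cells, and the channel Kcnk13 at 5.66 (3.17 to 10.98), each with 1 control UMI, then the kinase Fam20c at 4.53. Ear1, a ribonuclease with near-identical copies, was at -4.12, the flagellin receptor Tlr5 at -3.96 and Acaa1b at -3.28. Clusters 9 and 11 held 51.2% and 41.6% of the control cells, and clusters 2 and 7 held 58.4% and 28.2% of the Goblet-Y/T cells.

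Interstitial macrophages, 82 and 492 cells, had higher alternative activation and lower interferon response genes in the Goblet-Y/T library. Alternative activation genes were higher in 9 of 10, with a median of 1.01 (0.51 to 1.51), among them Arg1 at 2.91 (2.63 to 3.20) and the eosinophil attractant Ccl24 at 1.98. Interferon response genes were lower in 10 of 12, with a median of -1.04 (-1.20 to -0.41), and the chemokine Cxcl9 was at -5.32. The Cxcl9 ratio rested on few cells, with a UMI in 2.56% (0.312 to 8.96) of 78 control and 1.20% (0.390 to 2.78) of 417 Goblet-Y/T cells thinned to 3500 UMIs, with 4 and 75 left out, so the intervals overlapped. Unthinned shares were 2.44% and 1.63%, with median depths of 8341.5 and 7730.5 UMIs, and mesothelial cells thinned alike had 0.177% and 0.133%. Spp1 was at 3.89, but it was higher in all 10 other classes too, with a median ratio of 3.02, and stood at 0.934 of the CPM of the whole library. The proteoglycan Vcan, also a marker and a top gene of classical monocytes, was at 3.51 (1.63 to 6.57), from 136 UMIs against 2. The protease inhibitor Timp1 had 253 UMIs against 0, a log2 ratio of at least 3.82 against the floor of 3 counts over the class, where the counting interval began at 3.51. Timp1 was higher in all 6 other classes measured too, with a median ratio of 1.80, and stood at 0.812 of the CPM of the whole library. The chemokine Ccl5 was at -2.71, the prostaglandin-degrading Hpgd at -2.65 and Cyr61 at -2.13. Cluster 12 held 87.8% of control and 87.6% of Goblet-Y/T cells. The alternative activation median came to 0.14 with each library clustered alone, 0.42 with doublets kept and 0.40 with cells weighted equally, and Ccl5 turned to 0.92 with doublets kept.

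Ciliated cells, 1451 and 875, had higher interferon response genes in the Goblet-Y/T library, 13 of 14, with a median of 1.23 (1.04 to 1.61). Isg15, a ubiquitin-like interferon-induced protein, was at 4.13 (3.62 to 4.68), the immunity-related GTPase Iigp1 at 5.09 (4.07 to 6.33), the sensor Zbp1 at 2.52 and Ifit3 at 2.41. Few unthinned cells had a UMI of the first 2, with Isg15 in 5.37% of Goblet-Y/T and 1.38% of control cells and Iigp1 in 7.09% and 0.414%. No background class stands beside these shares, and free RNA was estimated at 7.63% and 10.1% of the UMIs. They therefore do not show how many cells expressed either gene. All 7 MHC class II genes were higher, with a median of 2.83 (2.49 to 2.98), and Sectm1a was at 3.69. The lowest ratios were those of Abca1 at -3.25 (-3.50 to -3.00), the cell cycle inhibitor Cdkn1c at -2.43 and the zinc finger gene Zfp955b at -2.12. Abca1 was lower in all 9 other classes measured too, with a median ratio of -1.63. Cluster 3 held 77.7% of the control cells and cluster 4 held 92.2% of the Goblet-Y/T cells.

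Mesothelial cells, 1154 and 1554, had higher cell cycle genes, 10 of 11, with a median of 3.00 (2.77 to 3.26), among them Mki67 at 3.13, Top2a at 3.00 and cyclin Ccnb1 at 4.50 (3.50 to 5.74). In cells thinned to 5000 UMIs, with 139 Goblet-Y/T and 42 control cells left out, Mki67 was detected in 2.76% (1.97 to 3.75) and 0.360% (0.0981 to 0.918), and in ciliated cells thinned alike in 1.49% (0.770 to 2.58) and 0.357% (0.116 to 0.832). Top2a was detected in 3.18% (2.33 to 4.23) and 0.989% (0.495 to 1.76) of mesothelial and 2.35% (1.42 to 3.65) and 0.858% (0.444 to 1.49) of ciliated cells, so for both genes the intervals of the 2 classes overlapped. Unthinned shares were 3.73% and 1.13% for Mki67 and 4.70% and 1.56% for Top2a in mesothelial cells, and 2.74% and 0.689% and 4.69% and 2.41% in ciliated cells, with median depths of 10302.5 and 13297 against 11193 and 11762 UMIs. Immediate early genes were lower in 14 of 15, with a median of -0.68 (-0.71 to -0.66), and Fos was at -0.68. Peripherin (Prph) was at 3.57, Tifa at 2.88, the kinesin Kif1a at 2.54, nitric oxide synthase Nos1 at -2.73, Abcb4 at -2.13 and the adhesion gene Pecam1 at -2.03. Cluster 5 held 71.7% of the control cells and cluster 1 held 79.2% of the Goblet-Y/T cells.

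In T cells, 213 and 138, all 11 cell cycle genes were higher in the Goblet-Y/T library, with a median of 1.64 (1.45 to 1.75). Tpx2, Cdc20 and Dtl, of mitosis and DNA replication, were at 2.25, 2.12 and 2.05, and Dapl1, the natural killer receptor chain Klrd1 and the antiproliferative gene Tob1 at -2.53, -1.85 and -1.83. Type 2 lymphocyte genes, 4 of 5 higher, had a median of 1.63 (1.03 to 2.15), which turned to -0.11 in thinned cells. In B cells, 91 and 112, all 11 cell cycle genes were higher, with a median of 1.35 (0.84 to 1.63), and Ube2c, Zcwpw1 and Cdk1 were at 2.79, 2.21 and 2.02. The chemokine Cxcl2 was at -2.37 in B cells but turned to 0.91 with doublets kept and 1.50 with each library clustered alone. It had a UMI in 11.0% of control and 30.4% of Goblet-Y/T B cells, so few control cells carried its UMIs and no direction is read from it, and Apoe and Pgap1 were at -2.25 and -1.81. Cluster 16 held 93.9% of control and 74.6% of Goblet-Y/T T cells.

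In adventitial fibroblasts, 172 and 185, which formed 1 cluster, genes of the extracellular matrix were higher in 8 of 11, with a median of 0.48 (0.43 to 0.57), and all 15 immediate early genes were lower, with a median of -0.58 (-0.82 to -0.52). The B cell attractant Cxcl13 was at 6.50 (3.99 to 11.81) from 108 UMIs against 1 but with a UMI in only 5.41% of the Goblet-Y/T cells, and was also a top gene of interstitial macrophage cluster 28. The class also had lubricin (Prg4) at 4.66, the chemokine Ccl8 at 4.56, the eosinophil attractant Ccl11 at 2.45 and Timp1 at 2.17. Prg4 was also a top gene of interstitial macrophage cluster 28, and Ccl8 of cluster 12. Ccl8 was higher in all 6 other classes measured, with a median ratio of 2.80, and Prg4 in 4 of 5, with 0.92. Neither gain was therefore particular to this class. The integrin Itga8, also a marker of alveolar fibroblasts, was at -4.28, Cdo1 at -3.61 and Bmp3 at -3.44, and Itga8 turned to 1.12 with each library clustered alone.

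Classical monocytes, 130 and 51, had higher MHC class II genes in the Goblet-Y/T library, 6 of 6, with a median of 2.58 (2.43 to 2.72), led by H2-Eb1, H2-Aa and H2-Ab1 at 3.41, 3.00 and 2.90. Unthinned, H2-Eb1 had a UMI in 29.4% of these 51 cells and 13.1% of the control cells. In mesothelial cells, which had more UMIs per cell, it had a UMI in 11.45% and 5.89%. These shares were therefore not read as shares of cells that expressed the gene. Mgl2, a top gene of the cDC2 cluster and of interstitial macrophage cluster 12, had 10 UMIs against 0, and the alveolar macrophage genes Fabp4 and Pparg had 1 against 77 and 4 against 43, so cells of other types in the class were not excluded. Interferon response genes were higher in 15 of 16, with a median of 1.08 (0.87 to 1.43). Cxcl9 had 55 UMIs against 0 in monocytes, a log2 ratio of at least 5.60 against the floor of 3 counts over the class, where the counting interval began at 5.25, and 5.88% of the 51 cells held all 55. Ldlrad3, Smc6 and Cxcl1 were at -1.98, -1.77 and -1.75, and the median gene of the class lay at -0.10. Neutrophils, 354 and 279, had lower interferon response genes, 10 of 12, with a median of -0.52 (-0.69 to -0.31), and higher granule genes, 8 of 9, with a median of 0.85 (0.61 to 1.45). The granule genes Camp and Ngp, at 3.08 and 1.97, turned to -0.69 and -0.74 with doublets kept. Scgb3a2, an airway secretory gene, was at 3.76 in neutrophils and at a median of 3.53 over 10 other classes. BC100530 and Setd5 were at 2.79 and 2.58, and H2-Q7, Gbp5 and Cd3d at -1.97, -1.47 and -1.40, where BC100530 and H2-Q7 have near-identical copies.

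**Figure D4:**
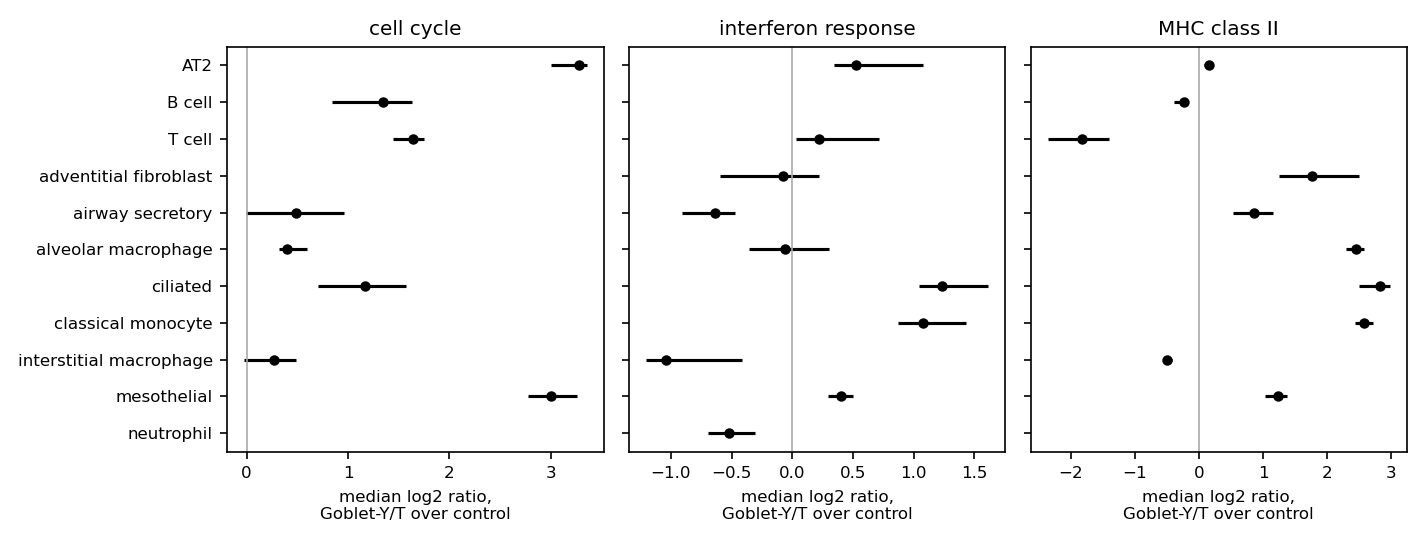
Median log2 ratio, Goblet-Y/T over control (x axis), of cell cycle, interferon response and MHC class II genes in each class with 5 or more measured members. Points are list medians and lines are 95% intervals of counting error. Cell cycle genes are highest in AT2 (3.28) and mesothelial cells (3.00), and interferon response genes lie on both sides of 0.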

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

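Tests chosen only after the result was seen were the comparison of airway secretory cells with other classes, the split by the cluster led by mucous genes, the comparison of AT2 with ciliated cells, the cytokine counts over all CD45-positive cells and the count of classes with higher sterol genes.

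With members past the free RNA rule, 3 of the fixed lists had classes in both directions with a median of at least 0.5 either way, an interval clear of 0 and a place outside the middle 95% of random lists, and the lowest and highest class of each are given. Other lists that went both ways did not meet these limits. Transitional epithelium genes had a median log2 ratio of -0.52 in airway secretory and 1.70 in AT2 cells, with the unrounded values -0.517 and 1.695. Interferon response genes stood at -1.043 in interstitial macrophages and 1.392 in ciliated cells, and endothelial activation genes at -0.6064 in mesothelial cells and 0.6229 in alveolar macrophages. These differences between classes were flagged by their direction and were not tested.

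Signals outside the class comparisons were flagged too. Over all CD45-positive cells, the type 2 cytokine Il5 had 303 UMIs against 11, a log2 ratio of 3.42 (2.56 to 4.44), and Il13 had 199 against 9, a ratio of 3.103 (2.15 to 4.25). These are not levels per cell of a type, since type 2 innate lymphoid cells made up 2.92% against 1.87% of the CD45-positive cells. That share was 1.56 times as high, below the 10.7 and 8.59 times of Il5 and Il13. Within type 2 innate lymphoid cells, Il5 had 300 of 759205 UMIs against 11 of 189881, and Il13 had 179 against 3. Both genes were among the markers that named this class. Scrublet called 7.418% of filtered Goblet-Y/T barcodes doublets, 760 of 10246, against 4.47% of control barcodes, 285 of 6371.

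YAP/TAZ target genes were lower in airway secretory cells of the Goblet-Y/T library. Set against the mean of AT2, ciliated and mesothelial cells, the median of 18 members was -1.06 (-1.30 to -0.84), which argues against a shift shared by all classes, although the signature was also lower in adventitial fibroblasts (-0.59), B cells (-1.39) and classical monocytes (-0.72). With the 20 most abundant genes, 58.6% and 54.2% of UMIs, left out of the totals it was -1.04 (-1.30 to -0.82), unrounded -1.044, which argues against a few genes taking most of the counts. Without the cluster led by mucous genes it was -1.08 (-1.41 to -0.83), unrounded -1.078. Within that cluster it was -0.48 (-0.86 to -0.26), whose upper end only just passed the bound of -0.25. A lower share of that cluster alone thus did not account for all of the difference. Outside it, cluster 20 held 153 control and 85 Goblet-Y/T cells and cluster 10 held 8 and 513. The value without it therefore compares mostly different clusters and cannot decide about their mix. The mix of clusters 10 and 20, the genotype and a difference between animals stay open and were not tested.

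Cell cycle genes were higher in AT2 cells of the Goblet-Y/T library. In the 603 of 2395 AT2 cells with 5 or more cell cycle UMIs, alveolar macrophage markers stood at 0.5881% of their level in alveolar macrophages, against 0.5632% in other AT2 cells, which argues against doublets with cycling macrophages. Summed cell cycle genes stood at 941.7 CPM in AT2 and 49.1 CPM in ciliated cells of that library, 19.18 times as high, which argues against free RNA. A difference in genotype and a difference between animals both stay open and were not tested.

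Sterol synthesis and uptake genes were higher across classes of the Goblet-Y/T library, with a median over 11 classes of 0.6828. It was 0.6814 in thinned cells. Thinning keeps each gene's expected share of a cell's UMIs, so this value cannot decide about a difference in UMIs per cell. With free RNA subtracted the median over classes was 0.4829, which argues against free RNA as the whole cause. The list was above 0 in 10.0 of 11 classes, all but B cells at -0.23, and a difference in handling between the 2 libraries cannot be told apart from a response of the tissue with 1 library per group.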

How the results depend on the processing

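Alternatives added only after the data were seen were the airway secretory cells split by the cluster led by mucous genes (number 19), those with 5000 or more UMIs, and list members past the free RNA rule. Of 2657 values under an alternative, 16 turned direction and a further 511 moved outside the counting interval of the main value. A turn was counted only where that interval was clear of 0, so the other 2641 can include changes of sign. Many gene values were picked as the highest or lowest of their class, so a kept direction was likely for them. Yap1 in airway secretory cells ranged from -1.86 to -0.79, Wwtr1 from -1.58 to -0.39, the YAP/TAZ target signature from -1.71 to -0.48 and goblet genes from 0.37 to 1.15. No paired analysis was possible because each group had 1 library. Lists in classes with few UMIs, such as neutrophils, rest on few members. For all values below, the cause was not tested.

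With doublets kept, Cxcl2 in B cells came to 0.9148, Ccl5 in interstitial macrophages to 0.9233, Camp and Ngp in neutrophils to -0.6866 and -0.7379, xenobiotic metabolism in airway secretory cells to -1.059, MHC class II in alveolar macrophages to 2.23, alternative activation in interstitial macrophages to 0.4215 and the interstitial macrophage share to 4.039 points. With each library clustered alone, Cxcl2 in B cells came to 1.5, Itga8 in adventitial fibroblasts to 1.119, Ccl17 in interstitial macrophages to -3.044, the IL-13 response in airway secretory cells to -0.04913, AT2 cell cycle genes to 6.478 and interstitial macrophage alternative activation to 0.1404. Shares then came to 24.57 points for AT2, 4.467 for airway secretory, 14.43 for alveolar macrophage, 2.096 for interstitial macrophage and 0.7223 for adventitial fibroblast cells. At resolution 2, shares were 4.753 points for airway secretory, 12.38 for alveolar macrophage, 5.037 for interstitial macrophage and 0.426 for adventitial fibroblast cells.

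In thinned cells, Areg and type 2 genes in T cells came to -0.1696 and -0.1115, the AT2 transitional and cell cycle lists to 1.532 and 3.448, xenobiotic metabolism to -0.8218 and the ciliated interferon response to 0.937. With cells weighted equally, Wwtr1 came to -1.584, the AT2 transitional list to 1.481, the unfolded protein response to 0.7541, xenobiotic metabolism to -0.8302 and interstitial macrophage alternative activation to 0.4016. The other scaling gave 1.465 for the AT2 transitional list and -1.076 for xenobiotic metabolism. With free RNA subtracted, the unfolded protein response came to 1.381 and alveolar macrophage MHC class II to 2.654. The ciliated interferon response was 1.02 and 0.9348 with members of 5 or more and 100 or more UMIs, and the YAP/TAZ target signature -1.71 with members past the free RNA rule.

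In the cluster led by mucous genes alone, Cldn18 came to 0.6444, Wwtr1 to -0.3923, Yap1 to -0.7947, the YAP/TAZ target signature to -0.4825, goblet genes to 1.148, the unfolded protein response to 1.296 and xenobiotic metabolism to -1.107. Without it, Scgb3a1 came to 1.405, Spdef to -0.06819, Yap1 to -1.864, goblet genes to 1.145 and xenobiotic metabolism to -0.4968. Up to 20% mitochondrial UMIs gave 3.419 for AT2 cell cycle genes, 200 or more genes per cell 0.5382 points for adventitial fibroblasts, and 1000 or more genes -3.974 points for neutrophils. Taken over all cells, shares were 13.35 points for AT2, -2.045 for T, 3.573 for airway secretory, 5.26 for alveolar macrophage, -0.9753 for basal, -14.62 for ciliated, 3.839 for interstitial macrophage and -2.875 for neutrophil cells.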

Other observations

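The cytokines counted over all CD45-positive cells and the share held by type 2 innate lymphoid cells were not part of the fixed design and were chosen after the data had been seen. Type 2 innate lymphoid cells, which release cytokines in response to epithelial alarmins, held 300 of 313 Il5 UMIs (95.8%) and 179 of 203 Il13 UMIs (88.2%) of the Goblet-Y/T library. In the control library they held 11 of 15 Il5 UMIs and 3 of 10 Il13 UMIs. Il5 and Il13 were among the markers used to name this class, so finding their UMIs in it was partly built in. Over all CD45-positive cells, Csf2, a growth factor of myeloid cells, was at a log2 ratio of 2.40 (1.71 to 3.17) and Areg, an epidermal growth factor family member, at 1.75 (1.65 to 1.86). The type 17 cytokine Il17a was at -2.95 (-3.76 to -2.20), from 60 and 20 UMIs, and interferon gamma (Ifng) at -1.82 (-2.28 to -1.37), while T cells made up 9.94% and 3.80% and natural killer cells 1.77% and 0.413% of the control and Goblet-Y/T CD45-positive cells, so they cannot be read as levels per cell of a type. Il4 had 7 and 14 UMIs, and Il9 and Il25 had 0 in both libraries.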
